A study of Mus musculus with 2 samples.

How the data were processed

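Single-cell RNA libraries were made from pooled aortic arches of male mice, per the labels' protocols: perfusion, tissue digestion for 15 minutes at 37 °C with the transcription inhibitor flavopiridol, sorting of live singlets and a PIPseq V3 T20 kit for up to 20000 cells. The protocol names 4 arches, 4 libraries and 4 hashtag antibodies, but the feature table holds 0 hashtag features, so cells could not be assigned to single mice. Each group is therefore represented by 1 sample, and the number of mice behind it cannot be read from the files. The values are whole-number counts per gene and barcode, which the authors deposited without normalization. Per the submitters' processing notes, STAR, Seurat 5 and the mm10 build were used, and the roles of these tools, the cell calling and the annotation release are not given in the sources used here. It is not stated that the counts are UMIs. They are treated as UMIs because the kit's molecules carry them.

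From the 32227 features, 32149 gene identifiers were matched to GENCODE M21 (GRCm38) for positions and spans, and 54 features share their symbol with another feature. Barcodes with fewer than 200 genes or over 20% mitochondrial counts were removed, and doublets were called by Scrublet in each library. Of 11341 and 1995 deposited barcodes (control and Lpl knockout), 8468 and 960 had under 200 genes, 5 and 0 were called doublets, and 2833 and 986 were kept, with 12989836 and 12431295 counts. The kept cells were normalized and log-transformed, and clustered together on 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 (seed 0). A cluster was named from marker lists when at least 3 markers were enriched 2 times or more and a marker stood among its first 30 genes by fold, without leading genes of another class. The names say which markers a cluster carries, hence the ending "-like". The enrichment and rank conditions were set after the clusters had been seen.

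Counts of a class were summed over its cells within a library and scaled to the class's total (CPM). Ratios (Lpl knockout over control) carry exact conditional 95% Poisson intervals, shares exact (Clopper-Pearson) binomial intervals, and a count of 0 is bounded by 3 counts. The ratio intervals treat each UMI as the counting unit, and the share intervals each cell. Both say nothing of variation between mice, and the ratio intervals also leave out variation between cells. No tests were therefore made, and no changed genes were counted from cells. Genes needed 20 UMIs over both libraries. The rule for named genes took up to 10 per direction in each class by the interval bound nearest to 1, among genes of at least 50 CPM and at least 20% of their level in the class where they were highest, leaving out other classes' markers and mitochondrial, ribosomal protein, haemoglobin, Gm and Rik genes. It also took up to 4 members of each fixed list with the largest log2 ratio, and Lpl, Ldlr, Gpihbp1, Cd36, Apoe, Angptl4, Plin2, Trem2, Abca1, Spp1, Vcam1 and Il1b in every case. Genes quoted outside this rule, such as Abcg1, Gpnmb or Cd74, and the genes whose counts in single cells are quoted, were chosen after their values were seen. Lists of genes were summarized by their median log2 ratio, the number of members at least 1.5 times higher or lower with an interval excluding 1, an interval from 200 Poisson redraws and a percentile among 10000 random lists matched in 20 bins of expression. A percentile matched on both expression and genomic span (5 bins each) was added after the data were seen. For shares of cells with a UMI, cells were thinned to 1000 UMIs, and for Lpl shares before thinning are given too.

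Groups, comparisons, gene lists, the named-gene rule and most alternatives were fixed before the data were examined. Classes needed 100 cells per group, and macrophage-like and monocyte-like cells were added after cell numbers were seen, with 40 as the limit. The alternatives changed cell filters, doublet removal, clustering, class naming, scaling, UMI minimums, thinning and the weight of each cell. The method was tested on simulated data with 200 genes changed. The intervals covered the true ratio for 96.1% of genes of macrophage-like cells, and 2.79% of unchanged genes passed 1.5 times with an interval excluding 1. Of genes changed by 1.5, 2 and 4 times, 35.4%, 70.3% and 95.2% were recovered. The simulated counts were Poisson draws of class sums, as the intervals assume, without variation between cells or mice. These rates therefore check the calculation and are not error rates for the real cells. Python 3.11.15, scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9 were used, with R 4.3.3 and edgeR 4.0.16 for TMM factors. Raw reads and the splicing state of transcripts were not used here, and classes with fewer than 40 cells per group were not compared gene by gene, except that B-like cells (150 and 30) entered the search for genes that differ in 5 classes at once.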

Results

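The data are single-cell RNA counts from mouse aortic arches, the curved stretch of aorta where plaques form early. Male mice lacking the LDL receptor (Ldlr) ate a western diet over 12 weeks, and their lipoprotein lipase gene (Lpl) was either intact or deleted by an inducible knockout. Each genotype has 1 deposited library, here called the control library (Ldlr knockout) and the Lpl knockout library (Ldlr and Lpl knockout). There are therefore no replicates: n = 1 per group throughout, no difference could be tested, and every interval below is a 95% interval for counting error only. The control library holds 49071867 counts over 11341 barcodes and the Lpl knockout library 18892850 counts over 1995 barcodes. Haemoglobin transcripts took 80.5% of the counts in the control library and 75.1% in the Lpl knockout library. After filtering, 2833 control cells with a median of 2858 unique molecular identifiers (UMIs) and 986 Lpl knockout cells with a median of 8515 UMIs were kept.

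The first comparison concerns the targeted gene. Lpl encodes the enzyme that hydrolyses triglycerides in circulating lipoproteins, and the series was designed to assess what unhydrolysed triglyceride-rich lipoproteins contribute to atherosclerosis. In the control library Lpl was concentrated in macrophage-like cells, which held 1993 of the 2037 Lpl counts of all kept cells. A Lpl count was found in 81 of 151 control macrophage-like cells (53.6%, exact binomial interval 45.4 to 61.8%) and in 4 of 68 in the Lpl knockout library (5.88%, 1.63 to 14.4%). With each cell thinned to 1000 UMIs the shares were 41.1% (33.1 to 49.3%) and 4.41% (0.919 to 12.4%). Thymocyte-like cells, which should lack Lpl, gave 2 of 824 control cells (0.243%) and 0 of 190 Lpl knockout cells, which allows a share of up to 1.58%. Median depths before thinning were 3691 and 2832.5 UMIs in the macrophage-like cells and 1981.5 and 3668 UMIs in the thymocyte-like cells thinned.

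Summed over macrophage-like cells, Lpl stood at 1520 CPM (counts scaled to the total of the class; 1454 to 1588) in the control library and 474 CPM (420 to 534) in the Lpl knockout library, a ratio of 0.312 (0.274 to 0.354). Of the 277 Lpl counts in Lpl knockout macrophage-like cells, 238 came from 1 barcode. Without the barcode fullest in Lpl in each library, the ratio was 0.0524 (0.0371 to 0.0720). Over all kept cells the ratio was 0.167 (0.148 to 0.188), and over all deposited barcodes 0.417. Erythroid-like cells held 4256309 of the 12989836 kept control counts and 8011179 of the 12431295 kept Lpl knockout counts. The ratio over all kept cells therefore also moves with the erythroid-like counts in its totals. Lpl (ENSMUSG00000015568) lies on chromosome 8 from 68880491 to 68907448 of the mm10 (GRCm38) assembly. The labels do not say which part of the gene was removed, so counts from 3' ends outside that part would not reflect the deletion. Lpl is among the genes that set the larger macrophage cluster apart. When cells were clustered without 45 such genes, an alternative added after the data were seen, 71 of 136 control (52.2%) and 4 of 64 Lpl knockout (6.25%) macrophage-like cells held a Lpl count.

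The next comparison asks which cells the arches yielded. Erythroid-like cells made up 16.6% of kept control cells and 35.2% of kept Lpl knockout cells, a difference of 18.6 percentage points (15.3 to 21.9). Thymocyte-like cells, marked by the recombinase gene Rag1, made up 29.1% (27.4 to 30.8%) and 19.4% (16.9 to 22.0%). T or NK-like cells made up 16.9% (15.5 to 18.3%) and 11.3% (9.35 to 13.4%). Macrophage-like cells made up 5.33% (4.53 to 6.22%) and 6.90% (5.39 to 8.66%), and monocyte-like cells 5.68% (4.86 to 6.60%) and 4.56% (3.35 to 6.06%). Fibroblast-like cells, expressing Dcn and Pi16, numbered 1 in the control library (0.0353%, 0.000894 to 0.197%) and 19 in the Lpl knockout library (1.93%, 1.16 to 2.99%). Endothelial-like cells numbered 23 (0.812%, 0.515 to 1.22%) and 18 (1.83%, 1.09 to 2.87%).

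Of named cells that were not erythroid, macrophage-like cells made up 151 of 2053 (7.36%, 6.26 to 8.57%) in the control library and 68 of 561 (12.1%, 9.54 to 15.1%) in the Lpl knockout library. No cluster was named smooth muscle, and 3 control and 7 Lpl knockout barcodes held counts of at least 3 of the 10 smooth muscle genes listed. Under a naming rule completed after the data were seen, 3 clusters stayed unnamed. They held 6.81% and 3.45% (led by Tenm2), 4.09% and 0.406% (led by Ccn3) and 0% and 4.06% (led by Galnt18) of control and Lpl knockout cells. The Tenm2 and Ccn3 clusters held counts of genes of smooth muscle, examined after the clusters were seen: Myocd, its transcriptional coactivator, stood at 795 and 1116 CPM of non-haemoglobin counts, Myl9 at 551 and 607, and Myh11 at 135 and 141. In these clusters Acta2 had 8 and 0 counts and Tagln 0 and 1. The endothelial-like cluster had 177 Acta2 counts (in 31.7% of its cells) and 51 Tagln counts (24.4%). Its sum of the 10 smooth muscle genes listed, 1006 CPM of non-haemoglobin counts, exceeded those of the Tenm2 (506) and Ccn3 (283) clusters. With all deposited barcodes and no filter, the differences for thymocyte-like cells (1.69 percentage points) and T or NK-like cells (1.48) pointed the other way. With at least 500 genes per cell, the erythroid-like difference was 1.00 percentage points, as erythroid-like cells hold a median of 232 and 283 genes.

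**Figure D1:**
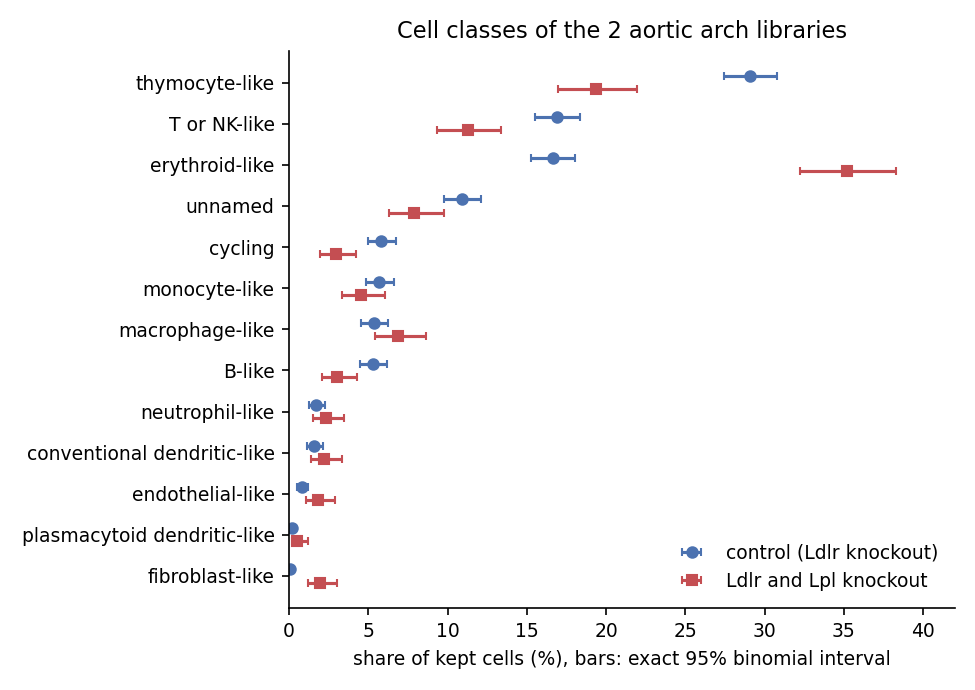
Share of kept cells (%) in each named class of the control library (circles, 2833 cells) and the Lpl knockout library (squares, 986 cells), with exact 95% binomial intervals as bars. Erythroid-like cells stand at 16.6% and 35.2% and thymocyte-like cells at 29.1% and 19.4%, while the intervals for macrophage-like cells overlap. Before filtering, barcodes of mostly haemoglobin counts were the larger share in the control library.

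In macrophage-like cells, the cholesterol exporter gene Abca1 was lower in the Lpl knockout library. This class has 151 and 68 cells, fewer than the 100 per group set beforehand, and was compared as an addition chosen after the cell numbers were seen. Abca1, the transporter that loads cholesterol onto apolipoprotein A-I, had a ratio of 0.541 (0.479 to 0.610) from 1386 and 334 counts. After thinning, Abca1 was detected in 49.7% (41.4 to 57.9%) of control and 23.5% (14.1 to 35.4%) of Lpl knockout macrophage-like cells, against 5.70% and 5.26% of thymocyte-like cells. Abcg1, a partner exporter to HDL, was detected in 57 of 151 (37.7%) and 14 of 68 (20.6%), against 15.4% and 11.6% of thymocyte-like cells, and had a summed ratio of 0.842 (0.749 to 0.946). Of 14 measured genes of cholesterol efflux and the liver X receptors (LXR), 4 were at least 1.5 times lower, 0 were higher and 10 were neither.

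The other lower members were the desaturase gene Scd2 (0.623, 0.451 to 0.849), the cholesterol esterification gene Soat1 (0.637, 0.525 to 0.768) and Arl4c (0.651, 0.467 to 0.894). The list's median log2 ratio was -0.25 (-0.42 to -0.16), at percentile 3.84 of random lists of like expression and 5.38 of lists matched also on genomic span. Abca1 spans 129 kb (ENSMUSG00000015243, chromosome 4, 53030787 to 53159895), and its ratio in thymocyte-like cells was 0.942. Scd2 was lower in thymocyte-like cells too, at 0.416. Plin2, a coat protein of lipid droplets, was higher at 1.33 (1.23 to 1.43), with 1.35 in thymocyte-like cells. Apoe, the apolipoprotein that clears remnants, stood at 0.861 (0.843 to 0.880) and the fatty acid receptor Cd36 at 0.759 (0.675 to 0.853). With every cell weighing the same, the ratios of Apoe (0.966) and Cd36 (0.954) were close to 1, while Abca1 stood at 0.382 and Plin2 at 1.47. Ldlr had 6 and 5 counts, Il1b stood at a ratio of 0.998 (0.558 to 1.73), Angptl4 at 1.16 (0.722 to 1.84), and Gpihbp1 had no count in this class in either library.

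**Figure D2:**
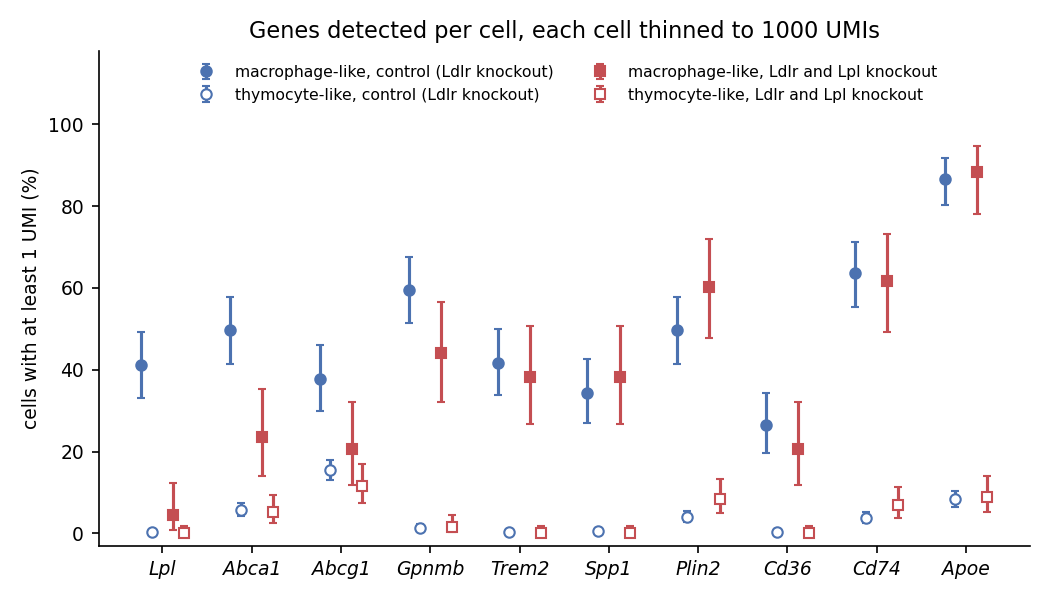
Share of cells (%) with at least 1 UMI of each gene after thinning every cell to 1000 UMIs, in macrophage-like cells (filled) and thymocyte-like cells (open) of the control library (circles) and the Lpl knockout library (squares), with exact 95% binomial intervals. Lpl stands at 41.1% and 4.41% and Abca1 at 49.7% and 23.5% of macrophage-like cells, while Trem2, Spp1, Cd74 and Apoe overlap.

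Of the other lipid gene groups in macrophage-like cells, 4 had medians with intervals that include 0. The triglyceride-rich lipoprotein handling list had a median log2 ratio of -0.10 (-0.31 to 0.10), with 3 of 17 genes higher and 3 lower. Among them the apolipoprotein gene Apoc1 was higher at 3.90 (2.75 to 5.58) and the monoglyceride lipase gene Mgll at 2.14 (1.75 to 2.61). The cell fullest in each gene held 48 of 92 and 132 of 195 Lpl knockout counts. The lipid droplet list stood at -0.25 (-0.59 to 0.14), sterol synthesis at 0.02 (-0.47 to 0.47) and fatty acid uptake and oxidation at 0.06 (-0.20 to 0.23). Each of these 4 medians changed sign or moved by over 1.5 times under some alternatives. The lysosome list stood at -0.22 (-0.36 to -0.19), with 9 of 30 genes lower and 0 higher, including the acid glucosidase gene Gaa (0.368, 0.217 to 0.594) and Hexb (0.532, 0.457 to 0.617).

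Several genes of the foamy, Trem2-positive macrophage state were lower in summed counts. Gpnmb, a glycoprotein of lipid-laden macrophages, had a ratio of 0.403 (0.383 to 0.424), the lysosomal protease gene Ctsl 0.215 from 9623 and 919 counts, the elastase gene Mmp12 0.403 (0.366 to 0.442), and the osteopontin gene Spp1 0.415 (0.389 to 0.442). The lipid receptor gene Trem2, at 0.721 (0.640 to 0.810), did not differ by 1.5 times. Of the 20 genes of this list 8 were lower, 1 was higher and 11 were neither, with a median of -0.34 (-0.39 to -0.26). Several of these genes lead the larger macrophage cluster. Clustered without them, the ratios were 0.388 for Gpnmb, 0.208 for Ctsl, 0.388 for Spp1 and 0.694 for Trem2. With every cell weighing the same, the list's median was 0.05, Spp1 stood at 0.864 and Trem2 at 0.966, while Gpnmb (0.479) and Ctsl (0.520) were still lower. Equal weight lets shallow cells count as much as deep ones. Macrophage-like cells were the only named class with a lower median depth in the Lpl knockout library (3691 and 2832.5 UMIs, 1695 and 1103 genes). In summed counts of cells with at least 500 genes, the list's median stayed negative. A few large cells carry much of the sum: 8 control and 5 Lpl knockout cells of over 30000 UMIs held 32.5% and 39.4% of the class's counts, and without them Ctsl stood at 0.506.

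Genes of the resident-like macrophage state were higher, 10 of 13 measured, with a median of 1.11 (0.95 to 1.52). They included the hyaluronan receptor gene Lyve1 (74.1, 19.7 to 625), the carbonyl reductase gene Cbr2 (8.12, 6.10 to 10.9) and the haemoglobin scavenger receptor gene Cd163 (5.66, 3.51 to 9.39). All Lyve1 counts came from 2 control and 5 Lpl knockout cells, and those 5 held 80.4% of the Lpl knockout counts of Cbr2 and 92.1% of those of Cd163. Within the Gpnmb and Trem2 cluster alone the list's median was -0.56. Genes of MHC class II antigen presentation were also higher in summed counts, 6 of 9, with a median of 0.94 (0.82 to 1.02), such as H2-Aa (2.34, 2.21 to 2.48) and the invariant chain gene Cd74 (1.91). With every cell weighing the same this median was 0.03, and Cd74 was detected in 63.6% and 61.8% of thinned cells, against 3.76% and 6.84% of thymocyte-like cells. The list's median was also positive in T or NK-like (0.81, 0.30 to 1.05), thymocyte-like (0.65, 0.24 to 1.24) and erythroid-like cells (1.01, 0.47 to 1.32). It was negative in monocyte-like cells. Members at least 1.5 times higher were 1 of 7 in T or NK-like, 3 of 7 in thymocyte-like and 4 of 5 in erythroid-like cells. Whether free RNA contributed there or in macrophage-like cells was not tested. The interferon response list stood at 0.68 (0.33 to 0.80), with 4 of 14 genes higher, among them Irf7 (2.03, 1.03 to 3.97), and at 0.07 with every cell weighing the same. Vcam1 stood at 1.61 (1.24 to 2.08) in summed counts and at 0.836 with every cell weighing the same.

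In macrophage-like cells, some inflammatory genes and most measured matrix protease genes were lower. The inflammatory cytokine list had 6 of 20 genes lower, 1 higher and 13 neither, with a median of -0.56 (-0.90 to -0.23), including the chemokine genes Cxcl2 (0.0275, 0.00744 to 0.0710) and Ccl2 (0.268, 0.180 to 0.388). In the control library, 7 cells marked by Prg4, Saa3 and Alox15 held 90.5% of the class's Cxcl2 counts and 53.8% of its Egr1 counts. This set was not found among the 68 Lpl knockout macrophage-like cells, and other classes were not searched. Of the 268 Ccl2 counts of the control library 125 came from 1 cell, and Ccl2 stood at 0.748 with every cell weighing the same. Matrix proteases had 6 of 9 genes lower and 1 higher, with a median of -0.99 (-1.40 to -0.69), and -0.53 with every cell weighing the same. Mmp19 stood at 0.194 (0.131 to 0.278) and the collagen-degrading cathepsin gene Ctsk at 0.267 (0.191 to 0.366), while the collagenase gene Mmp13 stood at 2.52 (1.41 to 4.50). Immediate early genes, which respond within minutes to stimulation and to tissue digestion, had 9 of 19 lower and 1 higher, with a median of -0.73 (-0.95 to -0.51). Egr1 stood at 0.0281 (0.00337 to 0.103) and Nr4a1 at 0.126 (0.0400 to 0.306). The immediate early median was -0.31 with at least 500 genes per cell, and -0.01 with called doublets kept, which redrew the clusters.

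Ribosomal protein genes (0.44, 0.41 to 0.48), complement genes (0.34, 0.27 to 0.61), ER stress genes (0.37, 0.21 to 0.46) and scavenger receptor genes (0.33, 0.03 to 0.44) had positive medians. For the ribosomal protein genes, lists matched on expression and span had a median of 0.28. The ER stress median was -0.01 without cells of over 30000 UMIs, the complement median 0.92 with at least 500 genes per cell, and the scavenger receptor median was -0.09 within the Gpnmb and Trem2 cluster alone. C1qa, which starts the classical complement cascade, had a ratio of 2.02 (1.89 to 2.16).

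**Figure D3:**
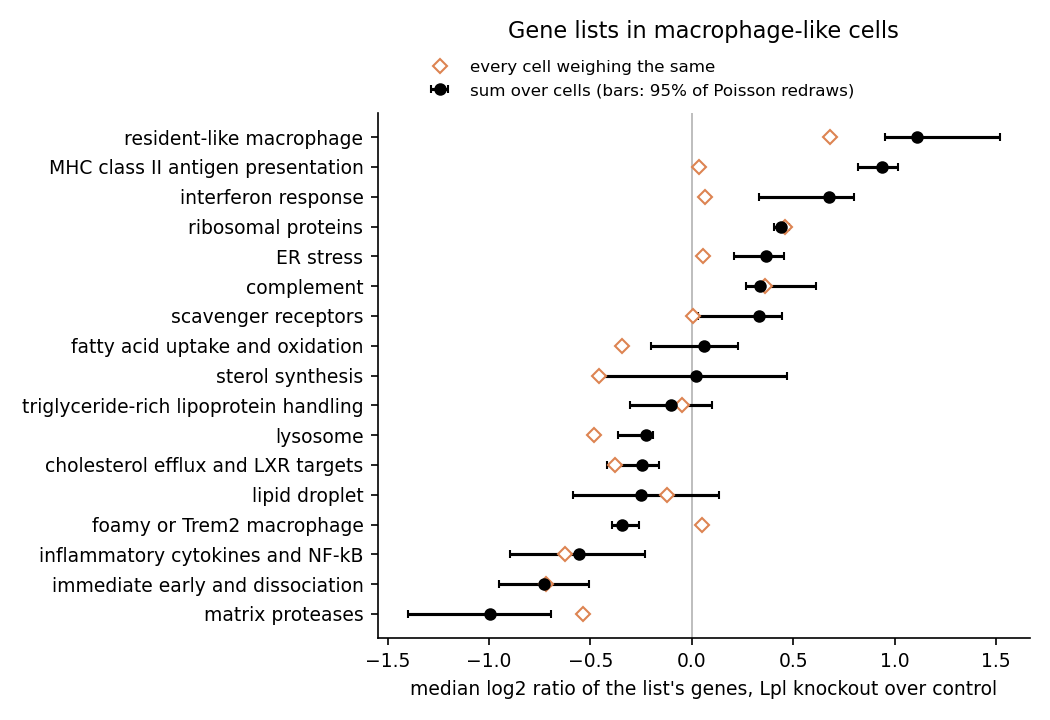
Median log2 ratio (Lpl knockout over control) of each gene list in macrophage-like cells, from counts summed over cells (filled circles, bars: 95% of Poisson redraws) and with every cell weighing the same (open diamonds). The cholesterol efflux and LXR list stands below 0 both ways (-0.25 and -0.38), while the MHC class II list stands at 0.94 and 0.03 and the foamy list at -0.34 and 0.05.

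Ranking genes of macrophage-like cells by the interval bound nearest to 1 mostly picked transcripts of a few cells. The leading lower genes were Slpi, Prg4, Saa3, Alox15, Serpinb2, F5, Tgfb2, Ptgis, Tafa2 and Thbs1. Prg4 encodes lubricin and Alox15 a lipoxygenase of peritoneal-type macrophages. In the control library 7 macrophage-like cells held at least 3 of Prg4, Saa3, Alox15, Serpinb2 and Ptgis, with 99.8% of the Slpi counts and 100% of those of Prg4. No Lpl knockout macrophage-like cell (0 of 68) did. With 7 of 151 control cells positive, an absence among 68 cells could arise from cell numbers alone. These genes lead the smaller macrophage cluster, which holds 37 control and 13 Lpl knockout cells. The leading higher genes were Rgcc, Xlr5a, Rcn3, Cbr2, Grm7, Fbxw2, Zfp981, Cd163, F13a1 and Ank3, of which Xlr5a had 29 of its 33 Lpl knockout counts in 1 cell and Grm7 75 of 87. Other list medians were -2.10 (-2.40 to -1.84) for 4 matrix genes including Fn1 (0.176, 0.150 to 0.206) and -0.78 (-1.26 to -0.28) for 10 endothelial adhesion genes. The same 7 cells held 69.9% of the class's control counts of Fn1, 96.9% of those of Ltbp1, 98.7% of those of Selp and 94.0% of those of Icam2.

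Monocyte-like cells (161 and 45, likewise added after the cell numbers were seen) had higher counts of genes of the foamy macrophage list in the Lpl knockout library. Fabp5, a fatty acid binding protein, had a ratio of 10.1 (8.75 to 11.7), and 790 of its 1253 Lpl knockout counts came from 1 cell. Its relative Fabp4 stood at 3.15 (2.46 to 4.05), the ferritin light chain gene Ftl1 at 2.76 (2.62 to 2.91) and Apoe at 1.64 (1.55 to 1.74). The foamy macrophage list had 11 of 15 genes higher and 0 lower, with a median of 0.91 (0.83 to 1.05) and 0.65 with every cell weighing the same. It was 0.24 with called doublets kept (5 control and 0 Lpl knockout), which redrew the clusters. This was not particular to monocyte-like cells: the list's median was 0.60 (0.36 to 0.80) in T or NK-like cells, with 6 of 12 genes higher and 0 lower, and 0.28 (0.11 to 0.50) in thymocyte-like cells, with 3 of 13 higher and 0 lower. The lipid droplet (-0.17, -0.58 to 0.36), cholesterol efflux and LXR (0.08, -0.17 to 0.25), sterol synthesis (-0.62, -1.42 to 0.01) and fatty acid (0.14, -0.06 to 0.38) medians had intervals that include 0. MHC class II genes were lower, 5 of 8, with a median of -0.83 (-1.06 to -0.58), such as H2-Aa (0.437, 0.353 to 0.537), and -0.35 with at least 500 genes per cell. Fn1, encoding fibronectin, stood at 0.208 (0.168 to 0.255) and the myeloid transcription factor gene Cebpb at 0.340 (0.289 to 0.399). Abca1 had 161 and 105 counts, a ratio of 1.16. The higher ranked genes were Tmprss9, Fabp5, Myo1d, Ms4a7, Acp5, Rgs1, H2-T23, Ftl1, Sdf2l1 and Aspscr1, and the lower ones Enpp2, Camk1d, Plxdc1, Mtcp1, Fn1, Supt20, Lars2, Txnrd1, Cdk8 and Cebpb. In the Lpl knockout library the cell fullest in each gene held 22 of the 23 counts of Tmprss9 and 47 of the 55 of Aspscr1. For Ms4a7 the fullest cell held 51 of the 75 counts and for Acp5 100 of the 191. The complement list stood at -0.72 (-0.96 to -0.19) and the ribosomal protein list at 0.64 (0.61 to 0.70). For the ribosomal protein list, lists matched on expression and span had a median of 0.37. A different scaling (TMM) moved all log2 ratios of this class by 0.12.

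Thymocyte-like cells (824 and 191) had higher counts of ribosomal protein, oxidative phosphorylation and heat shock genes in the Lpl knockout library. Ribosomal protein genes had 36 of 39 higher, with a median of 0.84 (0.81 to 0.87), such as Rpl3 (2.45, 2.19 to 2.74). Oxidative phosphorylation genes had 19 of 39 higher, with a median of 0.58 (0.49 to 0.65), such as Atp5b (2.05, 1.82 to 2.31). This median stood at percentile 94.9 of lists matched on expression and span. Such matched lists had medians of 0.46 here, 0.55 for the ribosomal protein genes and 0.38 for the heat shock genes. Part of each value is therefore shared by other genes of like expression and span. The mitochondrially encoded list had 2 of 13 genes higher and 1 lower, with a median of 0.24 (0.16 to 0.30). This lay below the 0.55 of its matched lists, at percentile 0.615. Heat shock genes had 7 of 8 higher, with a median of 0.75 (0.62 to 0.91), led by the chaperone gene Hspa8 (2.18, 1.93 to 2.46). Immediate early genes had 6 of 13 higher and 0 lower, with a median of 0.97 (0.52 to 1.33), such as Jun (3.53, 1.88 to 6.81) and Junb (69 and 84 counts, a ratio of 2.87).

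Of the ranked genes, Rftn1, a lipid raft protein, stood at 2.97 (2.64 to 3.35). Ctif, Draxin and Nip7 stood at 7.07, 3.61 and 3.65, with at most 2, 4 and 5 counts in any 1 Lpl knockout cell. The others (Ptpn11, BC025920, Cdkn3, Prr16, Lin28b and Zfp382) were carried by few cells, as for Ptpn11, with 192 of 259 Lpl knockout counts in 1 cell. The lower ones were Tafa2, Enpp2, Vwc2l, Mtcp1, Inpp4b, Crebrf, Gphn, Ric1, Arhgap15 and Lars2. Inpp4b, a phosphoinositide phosphatase, stood at 0.227 (0.172 to 0.294) and Arhgap15 at 0.305 (0.272 to 0.341). Totals without mitochondrial and ribosomal protein genes moved all log2 ratios of this class by 0.11.

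In T or NK-like cells (479 and 111), the leading higher genes included Ccl5, Gzma, S100a4 and Cd7. The chemokine gene Ccl5 stood at 2.42 (2.28 to 2.57), the granzyme gene Gzma at 2.72 (2.43 to 3.05), S100a4 at 3.58 (2.97 to 4.31) and Cd7 at 2.81 (2.25 to 3.52). The Gzma counts came from 28 control and 7 Lpl knockout cells, with 184 of the 684 Lpl knockout counts in 1 cell. The cluster led by Ccl5 and Gzma held 79 of the 479 control cells and 28 of the 111 Lpl knockout cells. A Tox and Lef1 cluster was the largest in the control library (213 cells), and a Ccr7 and Il7r cluster in the Lpl knockout library (56 cells). H2-T23, an MHC class I relative that binds an NK receptor, stood at 3.20 (2.71 to 3.79). Klra8, Cma1, Olfr1369-ps1, Vtcn1 and Shld2 were ranked too. The cell fullest in each gene held 43 of the 49 Lpl knockout counts of Klra8 and 59 of the 72 of Olfr1369-ps1. The lower ranked genes were Tafa2, Enpp2, Mtcp1, Gphn, Akt3, Inpp4b, Themis, Slc9a9, Lrba and Lars2, with the T cell selection gene Themis at 0.250 (0.219 to 0.286). The ribosomal protein median was 0.62 (0.59 to 0.64), against 0.35 for lists matched on expression and span. TMM scaling moved all log2 ratios by 0.19 and totals without mitochondrial and ribosomal protein genes by 0.18.

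Erythroid-like cells (471 and 347) differed in how much of their RNA was haemoglobin, with medians of 93.8% and 97.1%. The control cells lay mostly in a cluster led by Car2 and Slc4a1 (350 cells) and the Lpl knockout cells in clusters led by haemoglobin genes (142 and 135 cells). Slc4a1, the red cell anion exchanger, stood at 0.0882 (0.0746 to 0.104). The median log2 ratio of all measured genes was -1.57. It was -0.47 with totals without haemoglobin genes and -0.16 with TMM, shifts of 1.10 and 1.41. Against that background Atg4b, an autophagy protease gene, was higher at 21.4 (11.5 to 44.9), and AK157302 stood at 1.36 (1.17 to 1.58). The lower ranked genes besides Slc4a1 were Enpp2, Tafa2, Cmas, Lars2, Eif5, Cdk8, Wdr26, Specc1 and Hipk1.

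Many differences were shared by unrelated cell types. Of 2040 genes measured in macrophage, monocyte, thymocyte, T or NK and B-like cells, 26 were at least 1.5 times higher and 65 at least 1.5 times lower in the Lpl knockout library in all 5 classes. B-like cells, at 150 and 30, are the smallest of these classes. The higher genes included 13 ribosomal protein genes, the glycolytic enzyme gene Gapdh, H2-T23 and Atg4b. The lower ones included Enpp2, encoding autotaxin, Tafa2, Mtcp1, Camk1d, Lars2, Cdh13, Gphn and Akt3. In the control library Enpp2 stood at 100.6 to 205 CPM and Tafa2 at 82.5 to 196 CPM over 10 named classes. Erythroid-like cells were among them, at 172 and 158 CPM. The lower ratios of these 2 genes are therefore not particular to a class, and free RNA in the control library was not tested as their source. Ratios were lower for genes of longer genomic span. In thymocyte-like cells the median log2 ratio was 0.45 for the 20% of genes with the shortest spans and -0.70 for the 20% with the longest, and in macrophage-like cells 0.21 and -0.31. In erythroid-like cells the longest genes stood higher (-0.91) than the shortest (-1.33). Across these genes, which are not independent replicates, the ratios of macrophage and thymocyte-like cells had a Pearson correlation of 0.615 and a Spearman correlation of 0.601.

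**Figure D4:**
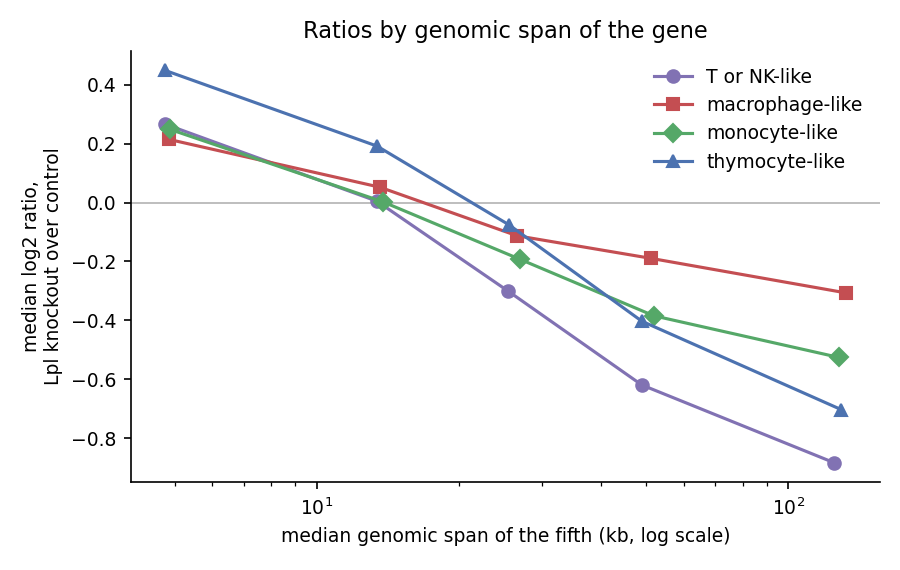
Median log2 ratio (Lpl knockout over control) of the measured genes in 5 equal bins of genomic span (kb, log scale), for macrophage, monocyte, thymocyte and T or NK-like cells, with lines joining the bins of a class. In these 4 classes the median drops from the shortest to the longest bin, from 0.45 to -0.70 in thymocyte-like cells and from 0.21 to -0.31 in macrophage-like cells.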

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

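The tests of a minority of cells that kept Lpl, of long genes, of a few large cells and of doublets were chosen only after the result was seen. Lpl counts remained in macrophage-like cells of the Lpl knockout library, 238, 27, 10 and 2 counts in 4 cells. Free Lpl RNA spread over all cells is argued against by the thymocyte-like cells of that library, whose Lpl CPM was 0.274% of that in macrophage-like cells, with an upper counting bound of 1.54%. A minority of cells that kept Lpl stays open: the 4 positive cells had a median of 5323 CPM. This lies inside the range of positive control cells (41.5 to 7073 CPM, median 1477). The range is so wide that this check could hardly have failed, so it does not decide the question. Cells of the control library among the Lpl knockout barcodes were not told apart from such a minority. The files share 0 barcode sequences, and how cells were assigned to libraries before deposit is not given. Genes that differ between the libraries in every class were not examined in these 4 cells.

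Genes lower in all 5 classes had a median genomic span of 125964 bp and genes higher in all 5 a median of 3999 bp. A few large cells are argued against, since with every cell weighing the same 83.5% of these genes kept a difference of 1.5 times in B-like cells, the lowest of the 5 classes, and 93.4% in macrophage-like cells, which hold the most cells of over 30000 UMIs. RNA of long genes, unspliced or primed within introns and captured in different amounts by the 2 libraries, may account for the pattern, as the median log2 ratio of the longest 20% of genes lay -1.15 from that of the shortest in thymocyte-like cells. Genotype and library are the same split here, so an effect of the Lpl deletion on these genes stays open and untested. Free RNA differing between the libraries was not tested for them either.

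Thymocyte-like cells formed a large class in both libraries, although the labels name aortic arch. After thinning, 55.8% of them (566 of 1014; 52.7 to 58.9%) held both Cd4 and a Cd8 gene, against 6.28% of T or NK-like cells, which is consistent with thymus tissue in the digested sample. Doublets of mature T cells are argued against, since cells with both had at most 0.649 times the median UMIs of T or NK-like cells. Rag1 stood at 1869 and 1286 CPM in thymocyte-like cells of the control and Lpl knockout libraries, and at 52.9 and 13.5 CPM in T or NK-like cells. Rag1 and the Cd8 gene Cd8b1 are among the markers that named the thymocyte-like clusters. The Rag1 levels, and in part the share with both Cd4 and a Cd8 gene, therefore follow from the naming. The labels give no biological explanation to set against thymus tissue, and none was tested.

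Some gene lists pointed in opposite directions in different classes, and none of these differences was tested. The foamy macrophage list's median log2 ratio in macrophage-like cells lay -1.25 from that in monocyte-like cells and -0.95 from that in T or NK-like cells, but with every cell weighing the same it was 0.049, on the side of the monocyte-like 0.65. For MHC class II genes the macrophage-like median lay 1.77 above the monocyte-like one, and was 0.034 with every cell weighing the same. The immediate early list's macrophage-like median lay -1.70 from the thymocyte-like one and -1.05 from the T or NK-like one (0.32), and was -0.0085 with called doublets kept. Galnt18 stood at 157226 CPM in the unnamed cells of the Lpl knockout library and at 160 CPM in those of the control library, a signal outside the classes compared. Of its 66286 counts there, 66254 lie in a cluster of 40 barcodes that holds 0 control cells and whose origin was not tested, so the unnamed cells of the libraries are unlike. Of the fibroblast-like cells of the Lpl knockout library, also not compared, 47.4% (9 of 19; 24.4 to 71.1%) held a Lpl count.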

How the results depend on the processing

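The alternatives on the Gpnmb and Trem2 cluster, the state genes, cells of over 30000 UMIs, the fullest Lpl barcode, haemoglobin-free totals and other share denominators, and equal cell weight for list medians, were chosen after seeing the data. Of 541 values from 57 results under 24 settings, 369 were called the same as the main value, 165 moved and 7 reversed. For differences, ratios and medians, the same meant inside the main value's interval for counting error. For counts of ranked genes it meant within 1.5 times. Of 447 differences, ratios and medians, 431 stayed on the main value's side of no change, and 63 of 70 counts of ranked genes stayed within 1.5 times. The Lpl ratio was below 1 in every setting run, and the cholesterol efflux and LXR median stayed between -0.38 and -0.19. Unless stated, the cause was not tested. With at least 500 genes per cell, differences in share were 1.00 (erythroid-like, which hold few genes) and -2.63 percentage points (T or NK-like), the Lpl ratio over all kept cells was 0.267, 7 ranked genes of erythroid-like (main 11) and 12 of macrophage-like cells (main 20) passed 1.5 times, and medians were 0.74 (ribosomal, thymocyte-like), -0.40 (foamy), 1.92 (resident-like), 1.15 (MHC class II) and 0.89 (interferon). With all deposited barcodes, differences reversed to 1.69 (thymocyte-like) and 1.48 (T or NK-like), and Lpl ratios were 0.228 (macrophage-like) and 0.417 (all cells). With a mitochondrial limit of 10%, 12 ranked macrophage genes passed, and at resolution 0.5, 13. With the 5 called control doublets kept, which redrew the clusters, 13 passed, and medians were -0.48 (foamy), 1.66 (resident-like) and 1.02 (interferon). Each sample clustered alone gave differences of -17.0 (thymocyte-like), -1.06 (T or NK-like) and 3.79 (macrophage-like). Classes by highest marker score gave 15.1 (erythroid-like) and -2.64 (T or NK-like), and thinning before clustering 14.8 and -1.49. Clustered without macrophage state genes, 12 ranked genes passed, and medians were -0.40 (foamy), 1.91 (resident-like) and 1.15 (MHC class II). Of named non-erythroid cells, differences were -6.09 (thymocyte-like) and 4.77 (macrophage-like), and outside erythroid and T-lineage classes 3.75 (macrophage-like), by their smaller denominators. The ribosomal median of thymocyte-like cells was 0.80 with TMM and 0.95 with totals without mitochondrial and ribosomal protein genes, and the Lpl ratio over all kept cells 0.311 with TMM. With every cell weighing the same, medians were 0.75 (ribosomal, thymocyte-like), 0.049 (foamy, reversed), 0.68 (resident-like), 0.034 (MHC class II) and 0.065 (interferon), Vcam1 reversed to 0.836, and the Lpl ratio over all kept cells was 0.408. With other classes' markers left out, the foamy median was -0.47. Without cells of over 30000 UMIs, medians were 1.74 (resident-like), 0.81 (MHC class II), 0.83 (interferon) and -0.0099 (ER stress, reversed). In the Gpnmb and Trem2 cluster alone, 11 ranked genes passed, and medians were -0.56 (resident-like, reversed), -0.087 (scavenger receptors, reversed), -0.43 (foamy) and 0.74 (MHC class II). Without the fullest Lpl barcode of each library, the Lpl ratio was 0.0524 (macrophage-like) and 0.0545 (all kept cells), since those barcodes hold much of the Lpl. The share of control macrophage-like cells with a Lpl UMI was 53.6% without thinning and 25.8% at 500 UMIs, by the depth alone. With a UMI minimum of 50, 17 ranked genes of macrophage-like, 18 of monocyte-like and 19 of T or NK-like cells passed, since the others have fewer UMIs. No paired analysis was possible because the groups share only replicate number 1. Depth limits what 68 macrophage-like cells of the Lpl knockout library can show.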

Other observations

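The search for wall cells, the sets of co-occurring genes and the span-matched percentiles below were chosen only after the result was seen. Fibroblast markers summed to 146 CPM of non-haemoglobin counts in the control library and 3119 in the Lpl knockout library. Endothelial markers summed to 415 and 616, and smooth muscle markers to 122 and 130. At least 3 fibroblast markers were held by 7 and 82 deposited barcodes, and at least 3 endothelial markers by 56 and 38. Fibroblast-like cells of the Lpl knockout library held 40 Lpl counts (155 CPM).

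The 7 control macrophage-like cells with at least 3 of Prg4, Saa3, Alox15, Serpinb2 and Ptgis had a median of 13491 UMIs. They held 99.5% of the class's Saa3, 95.5% of its F5, 77.1% of its Thbs1 and 69.9% of its Fn1 counts, and 98.7% of its counts of the adhesion gene Selp. The 5 Lyve1-positive cells of the Lpl knockout library held 78.0% of the class's counts of the coagulation factor gene F13a1 and 80.6% of its Rcn3 counts.

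Enpp2 and Tafa2 stood at 100.6 to 205 CPM and 82.5 to 196 CPM over 10 named control classes, and at 517 and 601 CPM in the unnamed control cells. Fibroblast-like and plasmacytoid dendritic-like control cells, with 1 and 5 cells, are left out of these ranges. The H2-T23 ratio was 2.16 to 3.75 and the Atg4b ratio 1.78 to 2.57 over macrophage, monocyte, thymocyte, T or NK and B-like cells, the lowest H2-T23 ratio being that of B-like cells (150 and 30). Against lists matched on expression and span, the oxidative phosphorylation median of thymocyte-like cells stood at percentile 94.9. In the 40 barcodes of the Galnt18 cluster, Galnt18 took 18.7% of the counts, and the SD of log2 Galnt18 over Gys1 across these barcodes was 0.48. Before filtering, 80.2% (79.5 to 81.0%) of control barcodes and 65.5% (63.4 to 67.6%) of Lpl knockout barcodes held over 50% haemoglobin counts.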
